A study of Mus musculus with 98 samples.

How the data were processed

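HSALR mice express a human skeletal actin transgene (hACTA1) that carries an expanded CUG repeat and are used as a model of myotonic dystrophy; FVB/NJ mice served as the wild type. The oligonucleotide is a (CAG)7 phosphorodiamidate morpholino oligomer (PMO), given unconjugated at 30 mg/kg or as the conjugate EEV4-PMO at 15 or 30 mg/kg, with PBS as the vehicle. RNA sequencing covered 98 libraries in 24 groups and 5 cohorts. The dose cohort held gastrocnemius at 7 days from FVB mice with PBS (n = 4), HSALR mice with PBS (n = 8), PMO at 30 mg/kg (n = 4) and EEV4-PMO at 15 and at 30 mg/kg (n = 4 each). A time course of EEV4-PMO at 15 mg/kg held gastrocnemius at 1, 2 and 4 days and quadriceps at 1, 2, 4 and 7 days, each with FVB and HSALR PBS groups of 4 days (n = 4 in every group). A further quadriceps cohort paired nascent RNA, labelled with ethynyl uridine (EU), with total RNA at 1 and 2 days of EEV4-PMO at 15 mg/kg (n = 3 each) and in HSALR PBS mice of 4 days (n = 4). The last cohort held quadriceps at 3 months after EEV4-PMO at 15 mg/kg (n = 6) or PBS (n = 4). Libraries were made after ribosomal RNA depletion with a directional kit, and the EU-labelled RNA and its total RNA were isolated with another extraction kit than the rest. P-values measure the spread between libraries as the labels give them.

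Expression was deposited by the authors as TPM, a transcript level corrected for length and scaled to the same total in each library, and 24528 genes with a value were read; 2 reporter entries without a value in some libraries were left out. Splicing was deposited by the authors as the fraction of transcripts that include an alternative sequence (percent spliced in, PSI, from 0 to 1) for 117460 events from rMATS, of which 87692 were skipped exons, 18041 mutually exclusive exons, 8256 alternative splice sites and 3471 retained introns by their coordinates. A separate table of the authors holds 36 exons, of which 29 had the same coordinates in the whole table, with a median absolute PSI difference of 0.006 and a largest of 0.5 between both tables. The submitters' processing notes name cutadapt, STAR and kallisto and the builds GRCm38 and mm10. TPM sums per library ran from 999972 to 999994, so a gene that takes more of a library lowers all others in it. Neither table holds read or junction counts, so the depth behind each value is unknown and no interval that needs it is given. Events with a value per library numbered 84817 to 88876 in the dose cohort, 67016 to 69523 in the gastrocnemius and 58335 to 69443 in the quadriceps time course, 77341 to 90112 in the EU cohort and 34114 to 34616 at 3 months. Exons were placed with the GENCODE vM21 annotation.

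Groups, tests, alternatives, gene lists and the rule for named genes were chosen before the data were examined. Exons were tested with limma 3.58.1 in R 4.3.3 on linear PSI, with 1 coefficient per group within a cohort, a trend in the prior variance and Benjamini-Hochberg adjustment, for events with a value in every library of the cohort. An event was called at an adjusted p under 0.05 and a difference in mean PSI of at least 0.1. Genes were tested with limma on log2 of TPM plus 1 for a mean TPM of at least 1, and called at an adjusted p under 0.05. There were 22 exon comparisons and 19 gene comparisons, all two-sided. The fit was checked against a separate calculation of the same model, and tested on simulated data with 100 changed features: a simulated PSI change of 0.3 was recovered in 80% of events for 30 mg/kg EEV4-PMO, 53% for gastrocnemius at 1 day and for quadriceps at 7 days, 49% for nascent RNA at 1 day and 30% at 3 months, and a log2 change of 1.58 in 92 to 98% of genes.

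A reference set was made of the 119 events, in 50 genes, that were called with the same sign between FVB and HSALR PBS in all 3 cohorts holding both; 53 were higher and 66 lower in FVB. The splicing rescue index of a library is the projection of its PSI values onto the FVB minus HSALR difference over this set, in percent, where 0 is the mean of HSALR PBS and 100 the mean of FVB. Events with a larger difference weigh more in the index. Genes with many events in the set, above all Neb and Tnnt3, therefore count for more than the other genes. Cohorts without FVB mice took the difference from the quadriceps time course, and the libraries at 3 months had a value for 101 of the 119 events. Groups were compared by exact permutation tests of the difference in means, where p is 2 times the smaller tail. The 28 index comparisons, but not single exons, had Benjamini-Hochberg adjustment. The smallest p these tests can give is 0.0286 for 4 against 4 libraries, 0.0571 for 3 against 4, 0.00404 for 4 against 8 and 0.00952 for 6 against 4. Replicate numbers paired nascent and total RNA: all 10 pairs correlated above 0.1 after group means were removed, and 9 of 10 best with their own number. The same check for gastrocnemius and quadriceps put every same-numbered pair above 0.1 in 4 of 6 comparisons, among them the treated groups at 1, 2 and 7 days but not at 4 days, and 19 of 24 libraries correlated best with their own number. The muscles were compared without pairs, as designed, and the differences within pairs are given beside that test. Correlations over genes used 100000 permutations.

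Named exons are the 10 called events with the largest difference in mean PSI whose groups do not overlap, 1 per gene, and a fixed set of exons known to be misspliced in myotonic dystrophy, taken from the authors' table of 36. Named genes are the 10 higher and 10 lower called genes with the largest change whose groups do not overlap and whose mean TPM reached 5 in either group, without predicted genes, plus the 4 members with the smallest p in each list; 1 gene that met this rule is not reported here. The 26 lists, fixed in advance and tested with camera of limma at a preset correlation of 0.01, were abundant sarcomere, adipocyte, circadian clock, denervation and atrophy, endothelial, excitability and calcium handling, extracellular matrix, fast glycolytic fibre, fibro-adipogenic progenitor, glucocorticoid and metallothionein, immediate early, interferon response, lymphocyte, lysosome and endosome, macrophage, neutrophil, nuclear noncoding RNA, oxidative phosphorylation, p53 response, red blood cell, regeneration and myogenic, Schwann cell, slow oxidative fibre, smooth muscle and pericyte, splicing regulators, and unfolded protein and integrated stress response. With a correlation estimated from the data, 0 lists passed in any of the 19 comparisons, the lowest adjusted p being 0.102, so list results below are preset-correlation calls.

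Alternatives were a minimum difference of 0.2, the logit of PSI bounded at 0.01 and 0.99, events with a value in at least 0.75 of the libraries of each group, fits of the compared groups alone, the replicate number as a block, a pseudocount of 0.1, no filter on TPM, TPM rescaled by a median of ratios, other exon sets, and each library left out in turn. After seeing the data, fits without a trend in the prior variance, with Xist over 10 TPM as a covariate, without 4 doubted libraries and with 1 exon per gene were added. The doubted libraries were gastrocnemius at 4 days of EEV4-PMO replicate 2 (lymph node and brown fat transcripts), nascent RNA at 2 days replicate 3 and quadriceps FVB replicate 3 (fewest events in their cohorts), and quadriceps FVB replicate 1 (adipocyte transcripts). Another library was first on that list for its low transgene level and was taken off, as that measure lies close to an outcome. The rule that sets an alternative index against the replicate SD, where no p under 0.05 can be reached, was changed after a first run. Software also included Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.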

Results

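Muscle of HSALR mice spliced a broad set of exons differently from wild-type muscle, and the labels ask how far and how fast an antisense oligonucleotide against the repeat returns these exons to the wild-type pattern. In gastrocnemius at 7 days, the 42-nucleotide exon of Atp2a1, the calcium pump of the fast sarcoplasmic reticulum (chromosome 7, 126446545 to 126446586), was included at 0.997 ± 0.001 PSI in FVB mice (SD, n = 4) and 0.190 ± 0.074 in HSALR PBS mice (SD, n = 8). This difference was 0.807 (adjusted p = 3.3e-13). The 79-nucleotide exon of Clcn1, the muscle chloride channel whose loss causes myotonia (chromosome 6, 42293444 to 42293522), was included at 0.202 ± 0.063 in FVB and 0.862 ± 0.054 in HSALR PBS (adjusted p = 5.2e-09). This value holds for 1 set of flanking exons, as the same exon with the flanks of the authors' table stood at 0.081 ± 0.014 and 0.559 ± 0.114. An exon of Ldb3, a protein of the Z-disc, was likewise lower in FVB (0.093 ± 0.012 against 0.821 ± 0.055, adjusted p = 5.0e-12). For Camk2b, a calcium-dependent kinase, an exon was higher (0.791 ± 0.047 against 0.142 ± 0.039, adjusted p = 5.8e-13). The largest difference, 0.961, lay in a mutually exclusive exon of Tnnt3, the fast troponin T, and Slc8a3, a sodium-calcium exchanger, Ogdh, an enzyme of the citric acid cycle, and Lrrfip2 differed by 0.762, 0.748 and 0.663. In all, limma called 495 of 46521 events, 255 higher and 240 lower in FVB. The same comparison called 199 of 48700 events in gastrocnemius at 4 days, with Atp2a1 at a difference of 0.639 and Mbnl1, the splicing factor held by the repeat, at -0.529. In quadriceps at 4 days it called 259 of 46493, with Clcn1 at -0.713 and Atp2a1 at 0.633. With a minimum difference of 0.2, 303 of the 495 were left, and fits of the compared groups alone called 93 events in gastrocnemius and 89 in quadriceps at 4 days.

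Expression set the genotypes apart as well. The transgene hACTA1 stood at 28450 ± 5126 TPM in HSALR PBS gastrocnemius at 7 days (SD, n = 8) and at 75 ± 4.46 TPM in FVB (SD, n = 4). The endogenous actin Acta1 did not pass the test (log2 change of 0.01 ± 0.05 SE, adjusted p = 0.95). FVB muscle had more Actc1, the cardiac actin (log2 5.26 ± 0.32), Kcnab1, a potassium channel subunit (2.53 ± 0.16), Pdlim7 (1.89 ± 0.09) and Pfkfb3, a regulator of glycolysis (1.75). It had less Sln, the sarcolipin that inhibits the calcium pump (-4.75 ± 0.36), Ankrd1, a stretch-responsive sarcomere protein (-3.16), Uchl1, a deubiquitinase (-3.15), Eda2r, a p53 target (-3.17), and Atf3, a stress transcription factor (-2.69). limma called 2855 of 13885 genes, 1220 higher and 1635 lower in FVB. Actc1, Kcnab1 and Pfkfb3 were also among the highest in FVB at 4 days in gastrocnemius (1179 genes, log2 3.89, 2.44 and 1.88) and quadriceps (1811 genes, 4.59, 3.32 and 2.23), and Sln and Ankrd1 among the lowest (-5.23 and -4.59, -4.42 and -3.73). The split at 4 days in gastrocnemius, 220 higher and 959 lower, became 489 and 624 after rescaling, which shifted the median of all genes by 0.108. Without HSALR PBS replicate 2 that count was 741, and fits of the compared groups alone gave 747 there and 841 in quadriceps.

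Gene groups were compared in the gastrocnemius at 7 days next. Fast glycolytic fibre genes were higher in FVB for 13 and lower for 2 of 20 (15 and 2 when adjusted over the list alone; adjusted p = 2.79e-06, and adjusted p = 0.31 with an estimated correlation). Tnnc2 stood at 0.57, Tnnt3 at 0.53 and Gpd1 at 0.71, against Myh1, a fast myosin heavy chain, at -1.69. Endothelial genes were higher for 9 of 13 (11 adjusted over the list alone), Cldn5 at 1.09 and Pecam1 at 0.46, with adjusted p = 2.47e-06, and adjusted p = 0.31 with an estimated correlation. Denervation and atrophy genes were lower for 6 of 13 (7 adjusted over the list alone; adjusted p = 0.000536, and adjusted p = 0.31 with an estimated correlation), Musk, the receptor kinase of the neuromuscular synapse, at -1.11 and Kcnn3 at -1.02. Of 14 p53 response genes 6 were lower and 1 higher (the same numbers adjusted over the list alone; adjusted p = 0.00805, and adjusted p = 0.31 with an estimated correlation), with Phlda3 at -1.80 and the cell-cycle inhibitor Cdkn1a at -1.23. None of the 11 Schwann cell genes was called, over all genes or adjusted over the list alone (0; median 0.62, adjusted p = 0.00824, and adjusted p = 0.605 with an estimated correlation). Of 11 smooth muscle and pericyte genes 3 were higher (7 higher and 1 lower adjusted over the list alone; adjusted p = 0.53 with an estimated correlation). Splicing regulators counted 1 higher and 4 lower of 17 (1 and 6 adjusted over the list alone; adjusted p = 0.211, and adjusted p = 0.801 with an estimated correlation). Abundant sarcomere genes counted 9 higher and 5 lower of 20 (9 and 5 adjusted over the list alone; adjusted p = 0.273, and adjusted p = 0.748 with an estimated correlation). In quadriceps at 4 days, adipocyte genes were higher in FVB for 3 of 10 (8 adjusted over the list alone; adjusted p = 0.000625, and adjusted p = 0.785 with an estimated correlation). Lep, the fat hormone leptin, stood at 7.42 ± 8.21 TPM against 0.696 and Scd1 at 542 ± 571 against 65.4 TPM. FVB replicate 1 stood apart with 19.6 TPM of Lep, against 2.06 to 5.07 in the others. At 4 days in gastrocnemius, regeneration and myogenic genes were lower for 4 and higher for 1 of 14 (7 and 1 adjusted over the list alone; adjusted p = 0.0456, and adjusted p = 0.539 with an estimated correlation).

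The dose cohort compares the conjugated with the unconjugated oligonucleotide in gastrocnemius at 7 days. At 30 mg/kg EEV4-PMO the Atp2a1 exon reached 0.912 ± 0.036 PSI (SD, n = 4; difference from HSALR PBS 0.722, adjusted p = 8.5e-12), and at 15 mg/kg 0.685 ± 0.053 (0.495, adjusted p = 2.5e-08). With unconjugated PMO at 30 mg/kg it stood at 0.159 ± 0.016. The Clcn1 exon fell to 0.296 ± 0.091 at 30 mg/kg (0.116 ± 0.021 with the flanks of the authors' table), and an exon of Tnnt3 (chromosome 7, 142507750 to 142507788) from 0.974 ± 0.028 to 0.236 ± 0.071 (adjusted p = 4.9e-12). At 15 mg/kg the Camk2b exon rose to 0.550 ± 0.025, and Slc8a3 and Mical3 exons rose by 0.559 and 0.446. limma called 390 events at 30 mg/kg (223 higher, 167 lower), 272 at 15 mg/kg (154 and 118) and 0 for unconjugated PMO, where 2781 of 46521 events had an unadjusted p under 0.05. EEV4-PMO and PMO at the same 30 mg/kg differed in 320 events, led by Slc8a3 (0.759), Atp2a1 (0.754, adjusted p = 6.6e-11) and Tnnt3 (-0.751). Between the doses 13 events were called. The largest difference lay in a noncoding exon of Ftx, an X-linked noncoding RNA (0.428 ± 0.332 at 30 mg/kg against 1.000 at 15 mg/kg, adjusted p = 0.016). More of the wild-type form was seen at 30 mg/kg in Tnnt3 (-0.397, adjusted p = 9.8e-06), Ldb3 (-0.243, adjusted p = 0.018), Atp2a1 (0.228, adjusted p = 0.018) and Ryr1, the calcium release channel (0.107, adjusted p = 0.025), the other 4 events named there. Those 13 were 7 with a replicate block and 0 in a fit of the compared groups alone, which gave 138 events at 15 mg/kg. For unconjugated PMO the count of 0 was 7 without PMO replicate 3, 5 without PMO replicate 1 and 3 without PMO replicate 2, and 3 on the logit scale.

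Most exons that moved with treatment moved toward the FVB level. Of the 390 events at 30 mg/kg, 290 were also among the 495 that differed between FVB and HSALR PBS, all in the same direction, and 199 of the 272 at 15 mg/kg. As both comparisons use the same PBS mice, the overlap was set against 3 values. Independent calls would share 2.1 and 1.5 events, a value that leaves the shared mice out of account. Simulated data without change shared 0. They were drawn around the observed PBS mean, so they cannot show an overlap that comes from the shared mice. With the PBS mice split so that each comparison had its own, 211 and 122 events were shared. The mean PSI moved in the direction of FVB for 365 events at 30 mg/kg and 233 at 15 mg/kg, and in the other direction for 1 each. These counts give the sign of the change and not the distance left to FVB. A further 24 and 38 had an FVB difference under 0.05. Against FVB itself, 58 events were still called at 30 mg/kg and 121 at 15 mg/kg. The rescue index over the 119 reference events was 73.0 ± 2.1% at 30 mg/kg and 50.2 ± 4.3% at 15 mg/kg (SD, n = 4 each), both above HSALR PBS (exact permutation p = 0.00404, the smallest possible; adjusted p = 0.0444). Unconjugated PMO stood at -3.2 ± 1.4%, within the spread of HSALR PBS (SD 6.5, n = 8; exact permutation p = 0.339). The doses differed by 22.8 points and EEV4-PMO and PMO at 30 mg/kg by 76.2 (exact permutation p = 0.0286 each, the smallest possible). A plot of the index per library shows these groups beside the time courses.

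**Figure D1:**
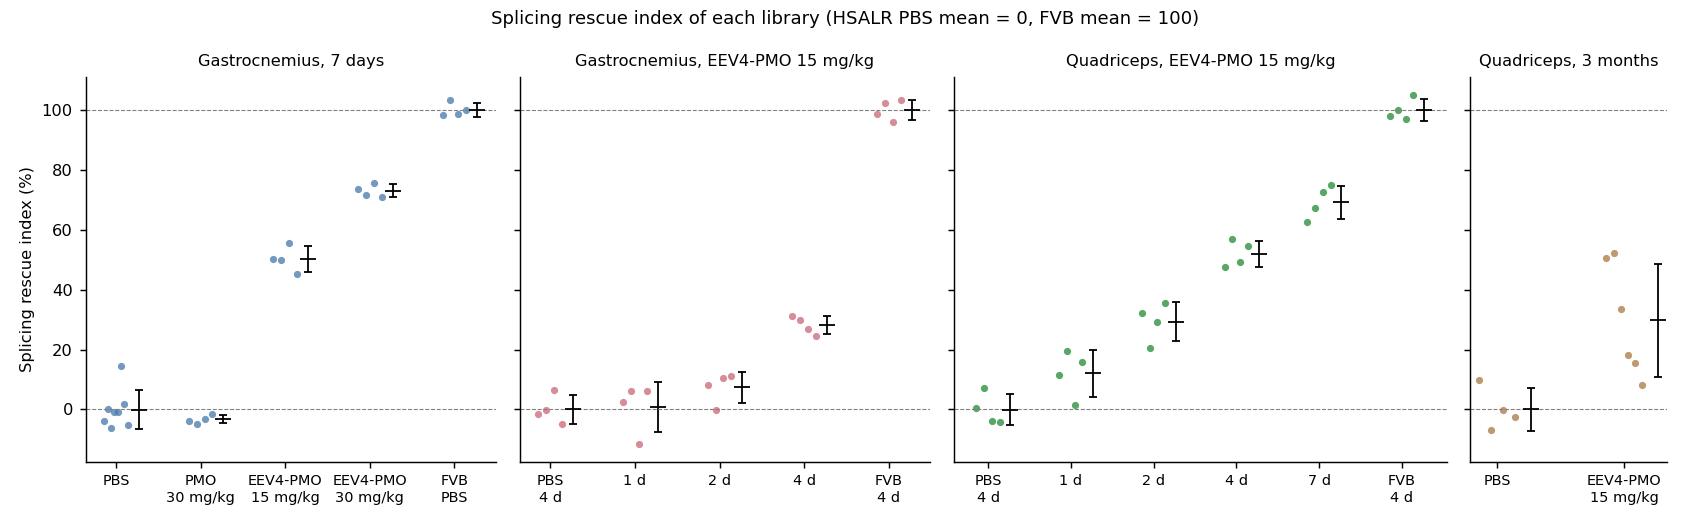
Splicing rescue index in percent (vertical axis, 0 at the mean of HSALR PBS and 100 at the mean of FVB) for each library by group, with 1 point per library. The EEV4-PMO groups at 7 days in gastrocnemius lay at 45.1 to 55.7% (15 mg/kg) and 71.0 to 75.7% (30 mg/kg), those with unconjugated PMO at -4.8 to -1.4%.

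Treated gastrocnemius at 7 days also changed its expression. Myh3, the embryonic myosin heavy chain, rose at 15 mg/kg (log2 1.49 ± 0.38, adjusted p = 0.014) and at 30 mg/kg (2.95 ± 0.38, adjusted p = 2.0e-05; 28.3 ± 12.4 against 2.69 ± 1.26 TPM, SD, n = 4 and 8). The embryonic light chains Myl4 (1.43) and Myl6b (1.45) and the matrix protein Postn (1.40) rose at 30 mg/kg, and Inmt, a methyltransferase, at both doses (1.89 and 1.91). The imprinted noncoding RNAs Rian and Meg3 fell at both doses (Rian -2.05 ± 0.17 and -2.53, Meg3 -1.65 ± 0.13 and -1.78), as did Tnfrsf12a, the TWEAK receptor (-1.55 and -2.46), Mustn1 (-1.11 and -2.56) and Myh1 (-1.28 and -1.82). limma called 1538 genes at 15 mg/kg (1095 higher, 443 lower) and 2089 at 30 mg/kg (1347 higher, 742 lower); rescaling turned these splits into 790 and 782, and 1033 and 1208. For unconjugated PMO 0 genes were called, with 1086 at an unadjusted p under 0.05, and 16 with a replicate block; without HSALR PBS replicate 8 the count was 8. Lysosome and endosome genes were higher for 7 of 19 at 15 mg/kg and 6 at 30 mg/kg (7 and 11 adjusted over the list alone; adjusted p = 0.00434 and 0.00889, and adjusted p = 0.753 and 0.871 with an estimated correlation). The cholesterol transporter Npc1 stood at 0.34 and 0.39 and Psap at 0.29 and 0.28. Among glucocorticoid and metallothionein genes 3 and 4 of 10 were higher (the same adjusted over the list alone; adjusted p = 0.753 and 0.871 with an estimated correlation), at 30 mg/kg Cebpd at 0.94 and Tsc22d3, a glucocorticoid-induced leucine zipper, at 0.70. With PMO none of the 3 measured neutrophil genes and none of the 3 red blood cell genes was called, adjusted over the list alone included (0 each; adjusted p = 0.197 and 0.044, and adjusted p = 0.794 and 0.68 with an estimated correlation). Without replicate 4, the count at 30 mg/kg was 1374, and a fit of the compared groups alone gave 938 genes at 15 mg/kg.

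The time course asks how soon splicing changes after EEV4-PMO at 15 mg/kg. In gastrocnemius the Clcn1 exon of the authors' table stood at 0.397 ± 0.169 PSI at 1 day, 0.311 ± 0.047 at 2 days and 0.213 ± 0.033 at 4 days, against 0.400 ± 0.056 in HSALR PBS and 0.060 ± 0.012 in FVB (SD, n = 4 each). The Mbnl1 exon went from 0.406 ± 0.060 in PBS to 0.391 ± 0.052, 0.320 ± 0.028 and 0.207 ± 0.051. The Atp2a1 exon was lower than in PBS at 1 day (0.225 ± 0.056 against 0.359 ± 0.064) and higher at 4 days (0.530 ± 0.058). For both, and Mbnl1 at 4 days, unadjusted exact permutation p was 0.0286. limma called 0 events at 1 and at 2 days (1997 and 1865 with an unadjusted p under 0.05). At 4 days it called 2, an exon of Ttn, the giant sarcomere protein titin (-0.207, adjusted p = 0.0047), and a mutually exclusive exon of Tnnt3 (0.106, adjusted p = 4.3e-04). The index was 0.8 ± 8.5% at 1 day, 7.5 ± 5.2% at 2 days and 28.1 ± 3.0% at 4 days (exact permutation p = 0.914, 0.0571 and 0.0286 against PBS). It rose by 20.7 points from 2 to 4 days (exact permutation p = 0.0286). At 1 day its sign turned to -1.1 with the 36 exons, and to -1.0 without treated replicate 2 or 4. The counts of events ran to 6 without PBS replicate 4 at 1 and at 2 days, and to 16 without PBS replicate 3 at 4 days, where fits of the compared groups alone called 0.

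Gastrocnemius expression was set against 4-day PBS, so treatment and day are not separated at 1 and 2 days. At 1 day Lcn2, an acute-phase protein, rose (log2 3.99 ± 0.78, adjusted p = 0.017, 57.7 ± 37.6 against 1.38 ± 0.644 TPM, SD, n = 4), with Socs3, a brake on cytokine signals (1.76), and Gadd45b (1.20). Ppara, a nuclear receptor of lipid metabolism, fell (-1.84 ± 0.24, adjusted p = 0.0029), as did the fatty acid carrier Fabp3 (-1.62 ± 0.36, adjusted p = 0.031), the lipid droplet protein Plin5 (-1.59), lipoprotein lipase Lpl (-1.51) and Pdk4 (-1.51). At 2 days Socs3 was still higher (1.27), the heat shock genes Hspa1a and Hspa1b were lower (-2.45 and -2.46), and Ppara and Lpl stood at -1.52 and -1.40. At 4 days Postn (2.88 ± 0.30, adjusted p = 3.4e-04) and Myh3 (2.49 ± 0.43, adjusted p = 0.017) rose, together with the antigen presentation genes Cd74 (2.61), H2-Aa (2.50) and H2-Ab1 (2.42). One of these 4 libraries, replicate 2, held transcripts of lymph node and brown fat. Lymphocyte genes had a median of 1.46 with 0 of 11 called (0 adjusted over the list alone; adjusted p = 0.00945, and adjusted p = 0.866 with an estimated correlation). Macrophage genes were higher for 1 of 14 at 4 days (6 adjusted over the list alone; adjusted p = 9.06e-07, and adjusted p = 0.672 with an estimated correlation). Slow oxidative fibre genes counted 0 of 16 at 2 days (14 lower adjusted over the list alone; adjusted p = 6.41e-11, and adjusted p = 0.377 with an estimated correlation). Immediate early genes counted 0 of 18 at 1 day (4 higher and 1 lower adjusted over the list alone; adjusted p = 0.878 with an estimated correlation). limma called 197 genes at 1 day (30 higher, 167 lower), 153 at 2 days (25 and 128, or 42 and 111 rescaled) and 74 at 4 days (45 and 29). Without 1 compared library, or 4-day treated replicate 2, these counts ran from 18 to 579, 29 to 496 and 15 to 78. The highest left out that replicate. Fits of the compared groups alone gave 75, 415 and 2, and a replicate block 36 at 4 days.

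Quadriceps responded sooner in the same time course. The Clcn1 exon of the authors' table went from 0.315 ± 0.049 PSI in HSALR PBS to 0.202 ± 0.131 at 1 day, 0.131 ± 0.040 at 2 days, 0.074 ± 0.024 at 4 days and 0.081 ± 0.025 at 7 days (SD, n = 4). These are 40.9, 67.0, 87.4 and 85.0% of the way to FVB. For Mbnl1 the same days gave 26.7, 67.8, 71.3 and 69.6%. An event of Bin1, a protein that shapes T-tubules, gave 35.2, 75.4, 93.4 and 97.0%, but matched no annotated exon. In the reference set Clcn1, with other flanks, stood at -0.1 and 48.5% at 1 and 2 days and Bin1 at -11.5 and 2.6%. Atp2a1 stood at 2.8, 30.3, 74.3 and 89.5%, Ryr1 at 1.1, 11.9, 45.5 and 78.0%, and a 303-nucleotide exon of Ttn (chromosome 2, 76705670 to 76705972) at 6.6, 20.8, 44.8 and 62.7%. limma called 0 events at 1 day (1831 with an unadjusted p under 0.05) and 2 at 2 days, in Reep1 (0.207, adjusted p = 0.046) and Ttn (-0.170, adjusted p = 0.018). There were 79 at 4 days, led by Ttn (0.632), Wwp1 (-0.518), Meis1 (-0.501) and Atp2a1 (0.469, adjusted p = 2.3e-04). At 7 days 143 were called, led by Tnnt3 (-0.751, adjusted p = 2.5e-10), Ttn (0.702), Neb, the thin-filament ruler nebulin (0.601), and Camk2b (0.569, adjusted p = 8.9e-09). The index was 12.1 ± 7.8, 29.4 ± 6.4, 52.0 ± 4.3 and 69.3 ± 5.5% at 1, 2, 4 and 7 days (SD, n = 4; exact permutation p = 0.0571 at 1 day and 0.0286, the smallest possible, later). It rose by 17.3, 22.7 and 17.3 points from each day to the next (exact permutation p = 0.0286 each); with the 36 exons the first step was 23.7 (exact permutation p = 0.0857) and the last 8.2 (exact permutation p = 0.143). The 2 events at 2 days were 0 with a replicate block and 45 without PBS replicate 2. Without treated replicate 4 the 79 at 4 days were 35 and the 143 at 7 days 92. Fits of the compared groups alone gave 22 and 50. The 0 events at 1 day were 6 without treated replicate 2.

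**Figure D2:**
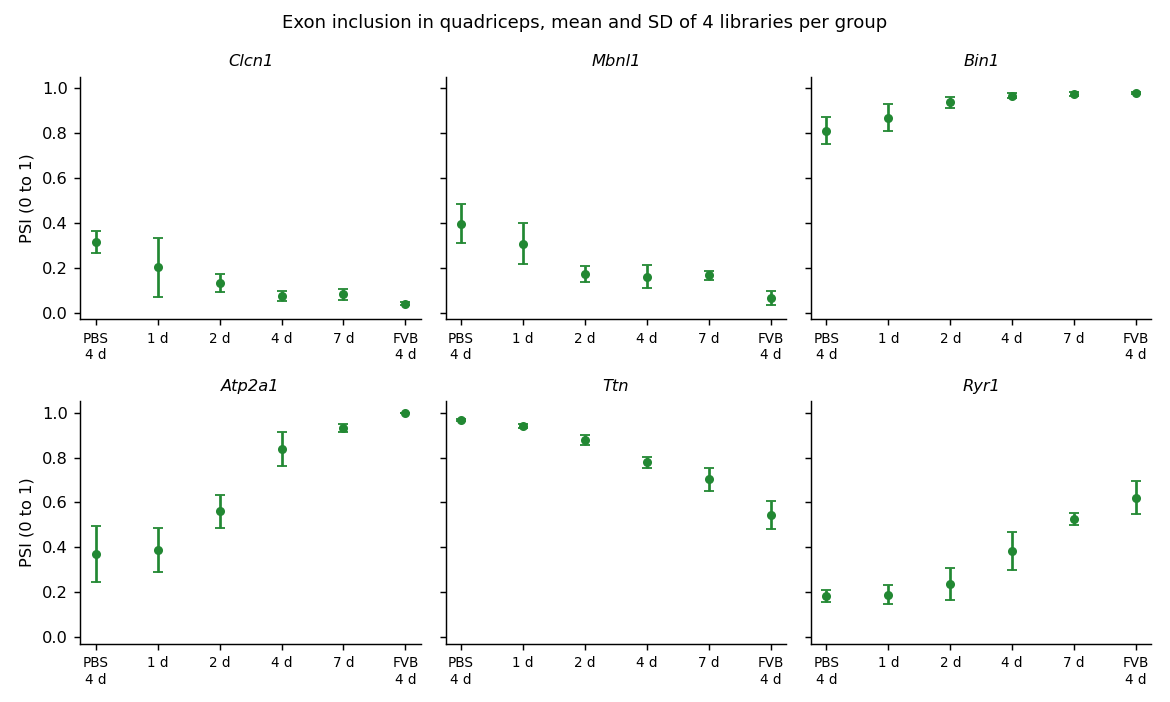
Mean PSI (vertical axis, from 0 to 1) of exons of Clcn1, Mbnl1, Bin1, Atp2a1, Ttn and Ryr1 in quadriceps of HSALR PBS, EEV4-PMO at 1, 2, 4 and 7 days and FVB mice (horizontal axis), with SD bars of 4 libraries. Clcn1 had gone 67.0% of the way to FVB at 2 days (48.5% with other flanks) and Ryr1 11.9%.

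Between muscles the index differed at matched days. Treated gastrocnemius lay 11.3 points from quadriceps at 1 day (difference -11.3, exact permutation p = 0.114) and lower by more at 2, 4 and 7 days (-21.9, -23.9 and -19.1, exact permutation p = 0.0286 each, the smallest possible; adjusted p = 0.0444). Same-numbered libraries of both muscles differed at 1 day by -9.0, -13.2, -13.1 and -9.7 points, all in 1 direction, and in all 4 pairs at each later day too, where 4 pairs cannot give an exact sign-flip p below 0.125. These tests permuted treated libraries alone, and the 7-day gastrocnemius came from the dose cohort. With the 36 exons the 7-day difference was -13.3 (exact permutation p = 0.0571). From 4 to 7 days gastrocnemius gained 22.1 points across the cohorts (exact permutation p = 0.0286).

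Quadriceps genes were set against 4-day PBS too, so treatment and day are not separated at other days. At 1 day the clock outputs Dbp (log2 1.30 ± 0.24, adjusted p = 0.013) and Per3 (1.12 ± 0.18, adjusted p = 0.0038) rose. The clock activator Arntl fell (-1.44 ± 0.30, adjusted p = 0.025), and so did Hspa1a and Hspa1b (-2.45 and -2.29). At 2 days Cish and Socs1, brakes on cytokine signals, rose (1.93 and 1.55), and Tnfrsf12a (-2.16 ± 0.32, adjusted p = 0.0014) and Atf3 (-2.11) fell. At 4 days the stress gene Gadd45a rose from 44.1 ± 16.9 to 628 ± 162 TPM (SD, n = 4; log2 3.84 ± 0.37, adjusted p = 1.2e-06). It was joined by the keratin Krt18 (3.38) and the acetylcholine receptor subunit Chrna9 (2.68 ± 0.54, adjusted p = 0.0028). At 7 days Chrna1, a subunit of the receptor at the neuromuscular synapse, rose (1.81 ± 0.30, adjusted p = 4.6e-04), as did Sln (2.30 ± 0.51, adjusted p = 0.0048; 906 ± 212 against 185 ± 54.2 TPM). Collagen Col1a1 fell (-2.14 ± 0.40, adjusted p = 0.0014). Rian fell at 4 and 7 days (-2.43, and -3.34 ± 0.30 with adjusted p = 7.8e-07), Meg3 too (-1.96 and -2.11), with Csrp3, a muscle LIM protein (-2.27 and -2.97). limma called 81, 255, 1199 and 1835 genes at 1, 2, 4 and 7 days. The splits at 1 and 2 days were 62 higher and 19 lower, and 162 and 93, or 78 and 69, and 124 and 238, after rescaling. At 1 day the count was 147 rescaled, 48 with a replicate block and 16 without treated replicate 2, and at 2 days 102 without treated replicate 4. At 4 and 7 days it was 792 without treated replicate 3 and 1211 without treated replicate 4.

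By gene group, denervation and atrophy genes in quadriceps were higher at 4 days for 8 of 13 (9 adjusted over the list alone; adjusted p = 1.02e-11, and adjusted p = 0.104 with an estimated correlation). Among them were the ubiquitin ligases Trim63 (1.80) and Fbxo32 (1.78) and the deacetylase Hdac4 (2.18). Extracellular matrix genes were lower at 7 days for 14 of 18 (16 adjusted over the list alone; adjusted p = 9.03e-12, and adjusted p = 0.428 with an estimated correlation), with Col3a1 at -1.75 and Col5a1 at -1.54. Fibro-adipogenic progenitor genes were lower for 4 of 11 (8 adjusted over the list alone; adjusted p = 7.53e-05, and adjusted p = 0.593 with an estimated correlation). Oxidative phosphorylation genes were lower for 11 of 19 (17 adjusted over the list alone, 8 rescaled; adjusted p = 2.67e-08, and adjusted p = 0.593 with an estimated correlation). Genes of the unfolded protein and integrated stress response were lower for 8 and higher for 1 of 14 (9 and 2 adjusted over the list alone; adjusted p = 0.299 with an estimated correlation), with the chaperone Hspa5 at -1.10 and Atf4 at -0.66. Excitability and calcium handling genes were higher for 8 and lower for 2 of 17 (10 and 2 adjusted over the list alone; adjusted p = 0.000155, and adjusted p = 0.428 with an estimated correlation). Clcn1 stood at 0.96, Ryr1 at 0.52 and the sodium channel Scn4a at 0.43. Circadian clock genes were higher for 6 and lower for 3 of 15 (8 and 3 adjusted over the list alone; adjusted p = 0.0188, and adjusted p = 0.428 with an estimated correlation).

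Nascent RNA, made during the EU label, was set against total RNA of the same quadriceps to ask whether new transcripts carry the corrected splicing earlier. At 1 day the Atp2a1 exon stood at 0.545 ± 0.010 PSI in nascent RNA and 0.326 ± 0.035 in total RNA (SD, n = 3), against 0.305 ± 0.075 and 0.257 ± 0.067 in HSALR PBS (SD, n = 4). In nascent RNA this was 38.3% of the way to FVB, in total RNA 11%. For the 303-nucleotide Ttn exon these shares were 20.5 and 2.9%, for Bin1 88.7 and 47.5%, for Nfix, a transcription factor of muscle development, 68.0 and 40.6%, and for Mbnl1 56.8 and 54.9%. Of the 14 exons of the fixed set 11 had the higher share in nascent RNA and 3 in total RNA, the latter in Phka1 (0.6 and 5.2%), Vps39 (76.8 and 109.5%) and Best3 (63.1 and 125.0%). At 2 days these numbers were again 11 and 3, with Bin1, Mbnl1 and Mbnl2 the lower ones in nascent RNA. In nascent RNA limma called 56 events at 1 day and 86 at 2 days. An exon of Mtmr1, a lipid phosphatase (chromosome X, 71379014 to 71379064), differed by 0.730 at 1 day (0.920 ± 0.138 against 0.191 ± 0.136, adjusted p = 0.0033) and 0.683 at 2 days (adjusted p = 0.0067), and one of Slc8a3 by 0.433 at 1 day (adjusted p = 0.046). In total RNA 1 event was called at 1 day, in Ttn (-0.113, adjusted p = 0.016), and 11 at 2 days, among them Ppp1r12b (0.351, adjusted p = 0.0013) and Mbnl1 (0.197 ± 0.059 against 0.468 ± 0.053, adjusted p = 0.017). A direct test of the treatment effect in nascent against total RNA called 2 events at 1 day, in Mccc1 (-0.121, adjusted p = 0.033) and Dcun1d4 (-0.116, adjusted p = 4.9e-05). It called 0 at 2 days, with limma giving 2168 and 2684 events at an unadjusted p under 0.05. With the paired replicate block these were 1 and 0 events. Both fractions shared 1 variance per event, so their counts are not compared. limma gave 4924 and 6053 nascent and 1223 and 1494 total RNA events at an unadjusted p under 0.05. In fits of the compared groups alone nascent counts were 0, below total RNA at 2 days, and with a replicate block 33 and 32. Without 1 treated library nascent counts ran to 204 and 517, total RNA to 13 and 25 and the direct test to 76 and 126.

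Over the reference set the index in nascent RNA was 22.2 ± 3.4% at 1 day and 35.2 ± 3.5% at 2 days. In total RNA it was 13.7 ± 3.2% and 30.1 ± 2.2% (SD, n = 3; exact permutation p = 0.0571 against PBS, the smallest possible). The level depended on the exons: the 36 of the authors gave 50.8 and 68.5% in nascent and 36.7 and 55.7% in total RNA, and 1 exon per gene gave 34.1 and 44.8%, and 22.4 and 40.2%. Paired by animal, nascent minus total RNA differed by 9.3, 8.0 and 8.2 points at 1 day and by -1.3, 9.4 and 7.2 points at 2 days, and in PBS animals by 2.1, -2.5, -0.4 and 0.8. The 6 treated animals averaged 6.8 ± 4.0 and the 4 PBS animals 0.0 ± 2.0 (SD; exact permutation p = 0.0381). The PBS mean of 0.0 is built in, as each RNA fraction was set against its own PBS mean, so only the spread was measured there. Taken alone, 1 day gave 8.5 points (exact permutation p = 0.0571, the smallest possible) and 2 days 5.1 points (exact permutation p = 0.229). This p rose to between 0.0635 and 0.0952 without any library other than those of replicate 1 at 2 days, and was 0.0159 without either of those; the 36 exons gave a difference of 13.4 (exact permutation p = 0.00952).

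**Figure D3:**
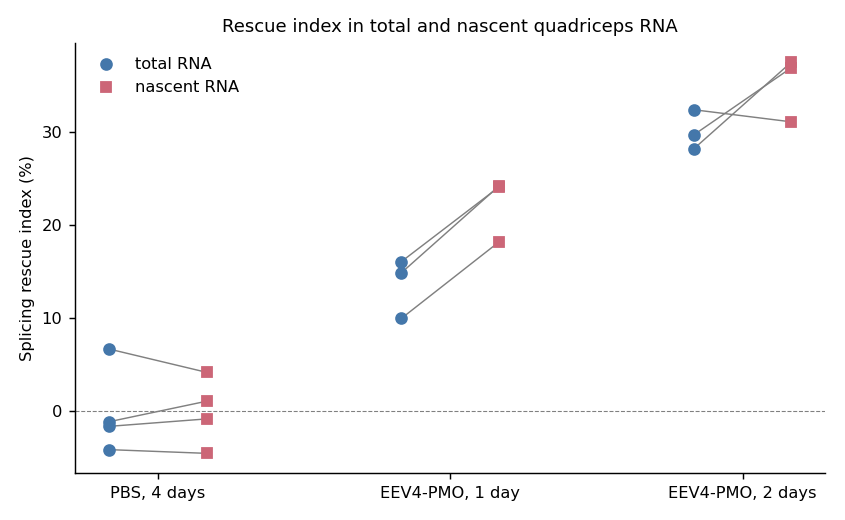
Splicing rescue index in percent (vertical axis) of total and nascent RNA from the same animal, joined by a line, for HSALR PBS and for EEV4-PMO at 1 and 2 days in quadriceps. At 1 day nascent RNA lay above total RNA in each of 3 animals, and at 2 days in 2 of 3.

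EU expression was set against 4-day PBS too, with the same limit. Lcn2 rose in total RNA at 1 day (log2 3.98 ± 0.34, adjusted p = 2.3e-05, 36.1 ± 16.4 against 1.36 TPM), and so did Pnmt (2.72 ± 0.34, adjusted p = 0.0033), the 2 genes called there. At 2 days Lcn2 (2.41), Pfkfb3 (1.79) and Tsc22d3 (0.97 ± 0.17, adjusted p = 0.015) were higher in total RNA, and Gadd45b (-2.19 ± 0.25, adjusted p = 0.0013) and the microfibril protein Fbn1 (-1.43 ± 0.26, adjusted p = 0.019) lower. Nascent RNA gained Lcn2 at 1 day (3.10 ± 0.34, adjusted p = 8.3e-04) and lost Myc, a growth regulator (-1.25 ± 0.25, adjusted p = 0.025). At 2 days it lost Gadd45b (-2.27 ± 0.25, adjusted p = 1.8e-04), Tnfrsf12a (-1.83) and the matrix-linked growth factor Ctgf (-1.78). limma called 82 genes in total RNA at 2 days (20 higher, 62 lower; 108 and 87 rescaled) and in nascent RNA 146 at 1 day and 869 at 2 days (177 and 692; 477 and 355 rescaled, a shift of 0.13). Total RNA had 6 genes at 1 day with a replicate block and 12 to 244 at 2 days without 1 library. Nascent RNA then had 24 to 784 at 1 day and 534 to 1361 at 2 days. In fits of the compared groups alone it had 20 and 24. The 244 and 784 left out 2-day nascent replicate 3. In PBS animals nascent RNA was richer than total RNA in nuclear noncoding RNAs for 7 of 8 (7 adjusted over the list alone, 7 higher and 1 lower rescaled; adjusted p = 0.0373, and adjusted p = 0.357 with an estimated correlation). Malat1 stood at 2.74 and Neat1 at 2.86, and nascent RNA was poorer in Hbb-b1, a globin chain (-4.12 ± 0.26). Of 11014 genes called between both RNA fractions 8229 were higher and 2785 lower in nascent RNA, or 5355 and 5445 rescaled, a shift of the median of -0.706.

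The series title points to transcript turnover, so rescue per gene was set against the ratio of nascent to total RNA. Across 50 genes of the reference set, rescue in total RNA of quadriceps at 1 day rose with the log2 nascent minus total level in PBS (Spearman rho 0.42, permutation p = 0.00246, adjusted p = 0.00492; Pearson r 0.39, permutation p = 0.00547). At 2 days rho was 0.26 (permutation p = 0.0714) and r 0.26 (permutation p = 0.0748), and with rescue from the EU total RNA rho was 0.29 (permutation p = 0.0441). Over the authors' 36 exons the values were rho 0.61 (permutation p = 1.2e-04) at 1 day and rho 0.28 (permutation p = 0.1) at 2 days, where r turned to -0.20 (permutation p = 0.255). Atp2a1, with a log2 ratio of -1.588, stood at 2.765% rescue at 1 day, Camk2b at -0.883 and 7.421%, Ldb3 at 0.407 and 27.356%, and Mbnl1 at 1.065 and 22.121%. Clcn1, with a ratio of 2.035, lay at -0.105% on the flanking exons of this set, against 40.9% for the same exon with the flanks of the authors' table. Genes are not independent replicates, and 2 such correlations were tested.

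**Figure D4:**
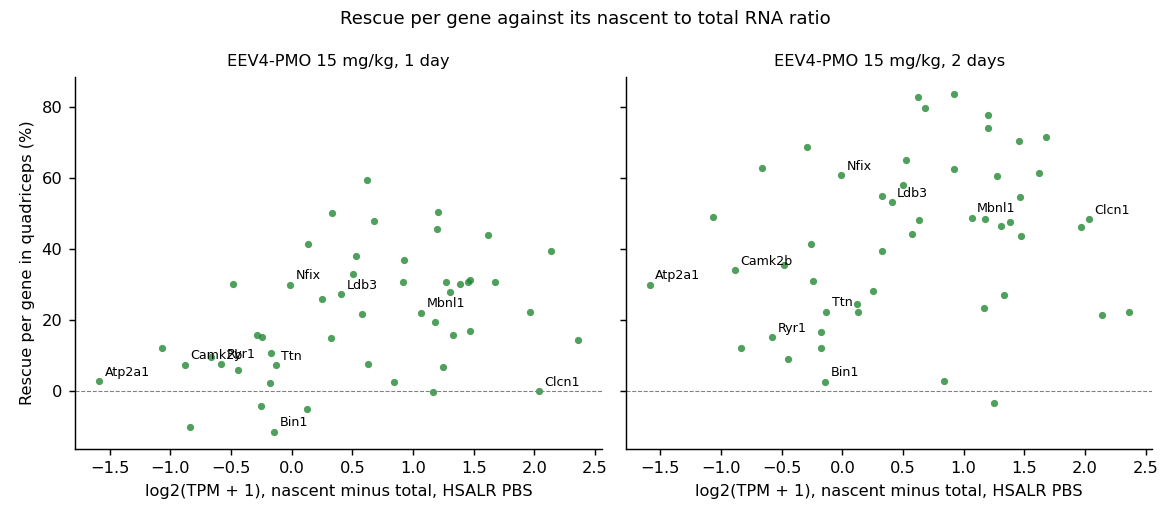
Rescue in percent at 1 day in quadriceps total RNA (vertical axis) against the mean log2 difference of nascent minus total RNA in HSALR PBS (horizontal axis), with 1 point for each of 50 genes. Atp2a1 and Camk2b lie at low ratios with 2.765 and 7.421%, and Clcn1 at a ratio of 2.035 with -0.105%.

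A later cohort asks how long the effect lasts, 3 months after dosing. The Atp2a1 exon stood at 0.591 ± 0.230 PSI in treated quadriceps (SD, n = 6) and 0.272 ± 0.112 in PBS (SD, n = 4; exact permutation p = 0.0286), 50.8% of the way to FVB. The Ttn exon was at 0.863 ± 0.049 against 0.940 ± 0.011 and that of Phka1, a subunit of phosphorylase kinase, at 0.287 ± 0.067 against 0.142 ± 0.017 (exact permutation p = 0.00952 each, the smallest possible). Mbnl1 was at 0.285 ± 0.098 against 0.470 ± 0.105 (exact permutation p = 0.0381) and Clcn1 at 0.301 ± 0.143 against 0.506 ± 0.128 (exact permutation p = 0.0667). The index, here over 101 of the 119 events, was 29.7 ± 18.7% and ranged from 8.2 to 52.1% (exact permutation p = 0.019, adjusted p = 0.0444; PBS SD 7.0). limma called 0 of 30966 events, with 1311 at an unadjusted p under 0.05, and 7 without PBS replicate 1. Of 1037 genes called, 1024 were lower, but rescaling, which shifted the median by 0.168, left 5 (3 higher and 2 lower). Tbata (-2.62 ± 0.27, adjusted p = 0.01), Meg3 (-1.36), Gadd45b (-1.15) and the mTOR inhibitor Ddit4 (-1.43) were lower as deposited. Rescaling kept the call of Tbata (-2.45, adjusted p = 0.037) and ended those of Meg3 (-1.17, adjusted p = 0.093), Gadd45b (-0.97, adjusted p = 0.069) and Ddit4 (-1.25, adjusted p = 0.081). The gene count was 0 without treated replicate 5 or PBS replicate 1, 3876 without treated replicate 1, and 1 with a replicate block. Interferon response genes counted 0 of 13 (0 adjusted over the list alone; adjusted p = 6.96e-05, and adjusted p = 0.759 with an estimated correlation).

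The transgene itself was lower after EEV4-PMO in the dose cohort. hACTA1 stood at 55.9% of HSALR PBS at 15 mg/kg (log2 -0.83 ± 0.13 SE, adjusted p = 2.5e-04) and 63.9% at 30 mg/kg (-0.63, adjusted p = 0.0018), and at 104.6% with unconjugated PMO (0.09, adjusted p = 0.92). In the gastrocnemius time course it was 100, 92.4 and 70.6% at 1, 2 and 4 days (adjusted p = 0.99, 0.98 and 0.32). In quadriceps it was 71.9, 59.2, 64.7 and 75.8% at 1, 2, 4 and 7 days (adjusted p = 0.65, 0.28, 0.3 and 0.47). Total RNA of the EU cohort held 45.2 and 49.7% and nascent RNA 48.9 and 64.7% at 1 and 2 days (adjusted p = 0.39, 0.074, 0.062 and 0.13). At 3 months it was 64.3% (log2 -0.69, adjusted p = 0.086), or log2 -0.50 rescaled (adjusted p = 0.47). The endogenous Acta1 did not pass in the dose cohort or time courses, and at 3 months stood at -0.34 (adjusted p = 0.036), or -0.15 rescaled (adjusted p = 0.46).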

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

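The tests on library composition at 3 months, on lymph node tissue at 4 days and on splits of the libraries were chosen after the results were seen, while those on the spread of the index at 3 months were written before. For the lymphocyte genes the criterion was also rewritten after its value was seen, as was that for the other genes of this muscle, and the sex test was redone by animal, and judged by the SD of permuted labels instead of p, after its values were seen.

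At 3 months 1024 of 1037 called genes were lower in treated quadriceps, and 2 transcripts, Gm20594 and Rn45s, the ribosomal RNA precursor, took 6.16 to 21.37% of the TPM in the 6 treated libraries and 1.75 to 3.42% in the 4 PBS libraries. With both left out and the rest scaled back to the same total, 9 genes were called (5 higher and 4 lower, 5 of them shared), and the median of all genes moved from -0.167 to -0.004. The lower calls may therefore reflect the share of these 2 transcripts rather than a loss of each RNA. A change of single genes with treatment stays open as a biological explanation and was not tested apart from this. Among 100 splits of the 10 libraries 2 gave as many genes and 1 of them 3242, which points to a structure of the samples other than treatment.

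In gastrocnemius at 4 days of EEV4-PMO the lymphocyte list had a median log2 change of 1.46 over 11 genes, none of which was called. This median was 0.04 without replicate 2. Lymph node tissue in that library could account for this part. A fit of all genes without that library argues against it as the cause of the rest: it called 53 higher genes outside the lymphocyte list (45 with it, 36 shared), a number that 1 of 35 splits of these libraries reached, the real one (highest other 1). Called genes in both directions then numbered 78 instead of 74, with 51 shared. Among the 10 named higher genes Postn stood at 3.11 and Myh3 at 3.05, while the antigen presentation genes dropped, Cd74 from 2.61 to 1.77 and H2-Aa from 2.50 to 1.68, so that library added to them. Hist1h3b, a histone, lost its call (2.96 to 2.71, adjusted p = 0.095). A response of the muscle to treatment stays open for these genes and was not tested further.

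The rescue index at 3 months spread from 8.2 to 52.1%, with an SD of 18.7 against 7.0 in PBS. Across the 6 treated libraries it fell with the log2 level of hACTA1 (r -0.93, exact permutation p = 0.0181, adjusted p = 0.0236; rho -0.94, exact permutation p = 0.0167; r -0.84 without the 2 farthest) and rose with the number of events with a value (r 0.71, exact permutation p = 0.0236, adjusted p = 0.0236; rho 0.89, exact permutation p = 0.0333; r 0.99 without the 2 farthest), the 2 correlations of this family. Mice with less repeat RNA may have more rescue. Each index used the same 101 events, so coverage did not alter which entered. The 2 measures were not separated. The 2 libraries with Xist, a mark of female animals, averaged 51.4% and the 4 without 18.9% (exact permutation p = 0.133, the smallest possible). Among 26 treated animals of the other cohorts, where same-numbered libraries of both muscles or both RNA fractions were taken as 1 animal, those with Xist lay 3.2 points lower within their groups (difference -3.2, SD of permuted labels 1.9, permutation p = 0.122, higher in 2 of 7 sets). Counted by library, the difference was -3.3 (SD of permuted labels 1.6, permutation p = 0.0445). Both lie below 0 by more than that SD, which argues against a higher index in animals with Xist as a general cause, while a difference of the sexes at 3 months alone stays open.

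Single libraries far from the rest of their group, by Dixon's test, were as follows, where chance puts about 1 in 20 groups past the value and 20 groups were tested per measure. HSALR PBS gastrocnemius at 7 days replicate 6 had a rescue index of 14.5% against -6.2 to 1.9% in the others. Gastrocnemius at 1 day replicate 3 had 26979 TPM of hACTA1 against 18505 to 19707. The share of TPM in the 10 highest genes was 21% in gastrocnemius at 7 days and 15 mg/kg replicate 4 against 24.6 to 24.8%, and 23.6% in gastrocnemius at 1 day replicate 3 against 21.9 to 22.1%. Events with a value numbered 84817 in HSALR PBS gastrocnemius at 7 days replicate 8 against 86763 to 88131, 58335 in quadriceps FVB replicate 3 against 67997 to 69443, and 34591 in treated quadriceps at 3 months replicate 1 against 34114 to 34224.

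Effects that differed between groups were the rescue index of gastrocnemius minus quadriceps at 2, 4 and 7 days (-21.9, -23.9 and -19.1 points), the rescue of nascent minus total RNA in treated minus PBS animals (6.8 points), and the treatment effect in nascent minus total RNA at 1 day for the Mccc1 event (-0.121) and the Dcun1d4 event (-0.116). For these 2 events chance was not excluded, and paired by animal only Dcun1d4 was called (adjusted p = 0.0121, and 0.0597 for Mccc1).

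Splits of the same libraries into groups of the same sizes gave a measure of chance for 41 counts, with EEV4-PMO at 15 mg/kg against HSALR PBS unless named otherwise. A share of splits under 0.05 was taken as unlikely by chance, without adjustment for the 41 counts, so chance is not excluded for each single count. Such a share was found for 29 counts, where in all but 1 only the real split (1 of 100, or 1 of 35) reached the count. For exons these were FVB gastrocnemius at 7 days (495, highest other 6), gastrocnemius at 7 days and 15 mg/kg (272, highest other 5) or 30 mg/kg (390, highest other 6) and EEV4-PMO against PMO at 30 mg/kg (320, highest other 3). Also reached by the real split alone were 30 against 15 mg/kg EEV4-PMO (13, highest other 3), FVB gastrocnemius at 4 days (199, highest other 2) and FVB quadriceps (259, highest other 2). Among treated groups they were quadriceps at 4 days (79, highest other 2) and 7 days (143, highest other 3), total RNA at 2 days (11, highest other 3) and nascent RNA at 2 days (86, highest other 58). For genes they were FVB gastrocnemius at 7 days (2855, highest other 71), gastrocnemius at 7 days and 15 mg/kg (1538, highest other 109) or 30 mg/kg (2089, highest other 454), FVB gastrocnemius at 4 days (1179, highest other 1), gastrocnemius at 1 day (197, highest other 1), 2 days (153, highest other 1) and 4 days (74, highest other 2). In quadriceps they were FVB (1811, highest other 5) and treatment at 1 day (81, highest other 12), 2 days (255, highest other 37), 4 days (1199, highest other 114) and 7 days (1835, highest other 1). The EU cohort added total RNA at 1 day (2, highest other 1) and 2 days (82, highest other 0), nascent RNA at 1 day (146, highest other 10) and 2 days (869, highest other 32), and nascent against total RNA (11014, highest other 2). The exception was quadriceps at 3 months, where 2 of 100 splits reached 1037 (highest other 3242), which points to a structure of the samples, so this count is not put down to treatment. For 12 counts the share was not under 0.05, and 7 of these counts were 0, which any split reaches, so the splits decide nothing there. These were the 0 exons (100 of 100) of unconjugated PMO (highest other 6) and of quadriceps at 3 months (highest other 2), the 0 genes (100 of 100) of unconjugated PMO (highest other 65), and the 0 exons (35 of 35) of gastrocnemius at 1 and 2 days (highest other 4 each), of quadriceps at 1 day (highest other 23, which points to a structure of the samples) and of the nascent minus total effect at 2 days (highest other 6). The other exon counts of this kind were gastrocnemius at 4 days (2, reached by 2 of 35, highest other 4), quadriceps at 2 days (2, reached by 2 of 35, highest other 2), total RNA at 1 day (1, reached by 17 of 35, highest other 2), nascent RNA at 1 day (56, reached by 2 of 35, highest other 62) and the nascent minus total effect at 1 day (2, reached by 10 of 35, highest other 6).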

How the results depend on the processing

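Of the alternative values, 224 exon counts and 215 gene counts lay within 1.5 times the reported count, and 147 and 98 did not. Among rescue indices and correlations, 163 alternative values kept direction and side of the threshold, 24 lost it, 12 moved by over the replicate SD, 1 passed it and 5 changed sign. A further 226 had an exact test that cannot go below p = 0.05, so only their direction and a move of less than the replicate SD were judged, and 142 of these stood at p under 0.05 as reported. For single named exons, 1706 of 1978 values kept direction and side, 272 lost the call and 0 changed sign, 55 of the lost calls in fits of the compared groups alone. For single named genes, 4897 of 5787 did so, 880 lost the call and 9 gained one, and hACTA1 in nascent against total RNA turned from 0.61 to -0.21 after rescaling. The settings without a trend in the prior variance, with Xist as a covariate, without the doubted libraries and with 1 exon per gene were chosen after seeing the data. The planned minimum of 20 junction reads was not run, as the values used hold no junction counts. TPM and PSI give no depth, so whether the number of reads limited a low count here is unknown. Except for the higher minimum difference, which can only remove calls, the cause of these moves was not tested.

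In the counts that follow, treated groups are compared with HSALR PBS at 15 mg/kg EEV4-PMO unless named otherwise, and the reported count stands in parentheses. A minimum difference of 0.2 in PSI gave exon counts of 303 for FVB gastrocnemius at 7 days (495), 130 for gastrocnemius at 7 days and 15 mg/kg (272), 225 for gastrocnemius at 7 days and 30 mg/kg (390), 199 for EEV4-PMO against PMO at 30 mg/kg (320), 1 for gastrocnemius at 4 days (2), 1 for quadriceps at 2 days (2), 51 for quadriceps at 4 days (79), 85 for quadriceps at 7 days (143), 0 for total RNA at 1 day (1), 7 for total RNA at 2 days (11), 34 for nascent RNA at 1 day (56) and 0 for the nascent minus total effect at 1 day (2). On the logit scale, exon counts were 3 for unconjugated PMO (0), 5 for 30 against 15 mg/kg EEV4-PMO (13), 3 for gastrocnemius at 1 day (0), 6 for gastrocnemius at 4 days (2), 2 for quadriceps at 1 day (0), 6 for quadriceps at 2 days (2), 2 for total RNA at 1 day (1), 33 for nascent RNA at 1 day (56), 4 for the nascent minus total effect at 2 days (0) and 5 for quadriceps at 3 months (0). Events with a value in at least 0.75 of each group's libraries gave 2 for unconjugated PMO (0), 2 for quadriceps at 1 day (0), 7 for quadriceps at 2 days (2) and 1 for quadriceps at 3 months (0). Fits of the compared groups alone gave exon counts of 138 for gastrocnemius at 7 days and 15 mg/kg (272), 190 for EEV4-PMO against PMO at 30 mg/kg (320), 0 for 30 against 15 mg/kg EEV4-PMO (13), 93 for FVB gastrocnemius at 4 days (199), 1 for gastrocnemius at 1 day (0), 0 for gastrocnemius at 4 days (2), 89 for FVB quadriceps at 4 days (259), 0 for quadriceps at 2 days (2), 22 for quadriceps at 4 days (79), 50 for quadriceps at 7 days (143), 0 for total RNA at 1 day (1), 6 for total RNA at 2 days (11), 0 for nascent RNA at 1 day (56), 0 for nascent RNA at 2 days (86) and 1 for the nascent minus total effect at 2 days (0). The same fits gave gene counts of 938 for gastrocnemius at 7 days and 15 mg/kg (1538), 747 for FVB gastrocnemius at 4 days (1179), 75 for gastrocnemius at 1 day (197), 415 for gastrocnemius at 2 days (153), 2 for gastrocnemius at 4 days (74), 841 for FVB quadriceps at 4 days (1811), 17 for quadriceps at 1 day (81), 97 for quadriceps at 2 days (255), 129 for total RNA at 2 days (82), 20 for nascent RNA at 1 day (146) and 24 for nascent RNA at 2 days (869). Without a trend in the prior variance, exon counts were 13 for gastrocnemius at 4 days (2), 19 for quadriceps at 2 days (2), 4 for total RNA at 1 day (1), 155 for nascent RNA at 2 days (86), 9 for the nascent minus total effect at 1 day (2) and 3 for the nascent minus total effect at 2 days (0). With Xist as a covariate, exon counts were 1 for quadriceps at 2 days (2) and 1 for the nascent minus total effect at 1 day (2), and gene counts were 1 for unconjugated PMO (0), 330 for gastrocnemius at 1 day (197), 208 for gastrocnemius at 4 days (74), 126 for total RNA at 2 days (82) and 2403 for quadriceps at 3 months (1037). Without the 4 doubted libraries, exon counts were 7 for gastrocnemius at 4 days (2), 2 for quadriceps at 1 day (0), 162 for nascent RNA at 1 day (56), 517 for nascent RNA at 2 days (86), 4 for the nascent minus total effect at 1 day (2) and 126 for the nascent minus total effect at 2 days (0), and gene counts were 2094 for FVB gastrocnemius at 4 days (1179), 579 for gastrocnemius at 1 day (197), 496 for gastrocnemius at 2 days (153), 131 for quadriceps at 1 day (81), 414 for quadriceps at 2 days (255), 244 for total RNA at 2 days (82) and 784 for nascent RNA at 1 day (146). No filter on low TPM gave 97 for gastrocnemius at 2 days (153), 121 for gastrocnemius at 4 days (74) and 665 for quadriceps at 3 months (1037) genes. Rescaled TPM gave 147 for quadriceps at 1 day (81), 195 for total RNA at 2 days (82) and 5 for quadriceps at 3 months (1037) genes. A pseudocount of 0.1 gave 96 for nascent RNA at 1 day (146) genes. With an estimated correlation, 0 gene lists passed in each of the 19 comparisons.

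The replicate block, a fit with the replicate number as an added factor, gave exon counts of 7 for 30 against 15 mg/kg EEV4-PMO (13), 0 for quadriceps at 2 days (2), 2 for total RNA at 1 day (1), 33 for nascent RNA at 1 day (56), 32 for nascent RNA at 2 days (86) and 1 for the nascent minus total effect at 1 day (2), and gene counts of 16 for unconjugated PMO (0), 36 for gastrocnemius at 4 days (74), 48 for quadriceps at 1 day (81), 6 for total RNA at 1 day (2) and 1 for quadriceps at 3 months (1037). It moved no other count by over 1.5 times. In 0 of the 18 compared group pairs did every same-numbered pair correlate above 0.1, and 20 of 68 libraries correlated best with their own number, so these groups share only a number. The gastrocnemius and quadriceps groups of 1, 2 and 7 days, where every pair did, kept mean differences of -11.3, -21.9 and -19.1 points in the pairs (exact sign-flip p = 0.125 each, the smallest possible). Paired within replicate numbers, all 28 index differences kept their direction, with 38.6 at 3 months (29.7) over the 4 shared numbers, and an exact sign-flip test of 4 pairs cannot go below p = 0.125.

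The exons of the authors' table of 36 gave rescue indices in percent of -1.1 for gastrocnemius at 1 day (0.8), 36.7 for total RNA at 1 day (13.7), 55.7 for total RNA at 2 days (30.1), 50.8 for nascent RNA at 1 day (22.2), 68.5 for nascent RNA at 2 days (35.2), 23.7 for quadriceps at 2 days minus quadriceps at 1 day (17.3), 8.2 for quadriceps at 7 days minus quadriceps at 4 days (17.3) and -13.3 for gastrocnemius at 7 days minus quadriceps at 7 days (-19.1), the last 3 with exact p = 0.0857, 0.143 and 0.0571. With the FVB difference taken from the dose cohort, the index of gastrocnemius at 1 day was -0.01 (0.8). With 1 exon per gene, indices were 22.4 for total RNA at 1 day (13.7), 40.2 for total RNA at 2 days (30.1), 34.1 for nascent RNA at 1 day (22.2), 44.8 for nascent RNA at 2 days (35.2) and 22.6 for quadriceps at 2 days minus quadriceps at 1 day (17.3), the last with exact p = 0.0571. The median over exons gave 37.5 for total RNA at 2 days (30.1), 28.6 for nascent RNA at 1 day (22.2) and 40.9 for nascent RNA at 2 days (35.2). Exons called in the quadriceps time course alone gave 25.8 for nascent RNA at 1 day (22.2). The nascent minus total difference of 6.8 was 9.9 with the median over exons (exact p = 0.105) and 6.4 without the doubted libraries (exact p = 0.0635), and 13.4 with the 36 exons (exact p = 0.00952) and 8.1 with 1 exon per gene (exact p = 0.0476). The correlation of rescue with the nascent to total ratio at 2 days passed p = 0.05 with rescue from the EU total RNA (rho 0.29, permutation p = 0.0441), and with the 36 exons its Pearson r was -0.20 (0.26).

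Without 1 library of the compared groups, these exon counts moved. Given are the reported count, lowest to highest value and, after each replicate number, the count without it. Unconjugated PMO (0) spanned 0 to 7, outside 1.5 times without PBS 5 (1) and PMO 1 (5), 2 (3) and 3 (7). Gastrocnemius at 1 day (0) spanned 0 to 6, outside 1.5 times without treated 2 (1) and 3 (3) and PBS 1 (3), 2 (2), 3 (2) and 4 (6). Gastrocnemius at 2 days (0) spanned 0 to 6, outside 1.5 times without treated 1 (1) and 3 (1) and PBS 1 (2), 2 (1) and 4 (6). Gastrocnemius at 4 days (2) spanned 2 to 16, outside 1.5 times without treated 2 (7) and 3 (7) and PBS 1 (5), 2 (6), 3 (16) and 4 (11). Quadriceps at 1 day (0) spanned 0 to 6, outside 1.5 times without treated 2 (6), 3 (3) and 4 (1) and PBS 1 (1), 2 (3), 3 (2) and 4 (3). Quadriceps at 2 days (2) spanned 1 to 45, outside 1.5 times without treated 1 (1), 2 (8), 3 (1) and 4 (1) and PBS 1 (9), 2 (45), 3 (4) and 4 (5). Quadriceps at 4 days (79) spanned 35 to 111, outside 1.5 times without treated 2 (39), 3 (52) and 4 (35) and PBS 1 (45), 3 (42) and 4 (45). Quadriceps at 7 days (143) spanned 92 to 150, outside 1.5 times without treated 3 (95) and 4 (92). Total RNA at 1 day (1) spanned 0 to 13, outside 1.5 times without treated 1 (6), 2 (13) and 3 (13) and PBS 1 (0), 2 (3), 3 (2) and 4 (3). Total RNA at 2 days (11) spanned 4 to 25, outside 1.5 times without treated 2 (19) and 3 (25) and PBS 1 (4), 2 (7) and 3 (6). Nascent RNA at 1 day (56) spanned 53 to 204, outside 1.5 times without treated 2 (204) and 3 (136). Nascent RNA at 2 days (86) spanned 49 to 517, outside 1.5 times without treated 1 (176), 2 (359) and 3 (517) and PBS 1 (49). The nascent minus total effect at 1 day (2) spanned 1 to 76, outside 1.5 times without total treated 1 (7), 2 (14) and 3 (12), total PBS 1 (1) and 2 (1), nascent treated 1 (22), 2 (76) and 3 (50) and nascent PBS 4 (1). The nascent minus total effect at 2 days (0) spanned 0 to 126, outside 1.5 times without total treated 1 (4), 2 (2) and 3 (7), total PBS 3 (1), nascent treated 1 (15), 2 (54) and 3 (126) and nascent PBS 1 (2), 3 (2) and 4 (2). Quadriceps at 3 months (0) spanned 0 to 7, outside 1.5 times without treated 5 (1) and PBS 1 (7), 2 (3), 3 (2) and 4 (1).

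Gene counts without 1 such library follow in the same form. Unconjugated PMO (0) spanned 0 to 8, outside 1.5 times without PBS 3 (4) and 8 (8) and PMO 2 (1). Gastrocnemius at 7 days and 30 mg/kg (2089) spanned 1374 to 2313, outside 1.5 times without treated 4 (1374). FVB gastrocnemius at 4 days (1179) spanned 741 to 1187, outside 1.5 times without PBS 2 (741). Gastrocnemius at 1 day (197) spanned 18 to 223, outside 1.5 times without treated 1 (28) and 4 (86) and PBS 1 (92) and 3 (18). Gastrocnemius at 2 days (153) spanned 29 to 97, outside 1.5 times without treated 1 (29), 2 (97), 3 (48) and 4 (54) and PBS 1 (65), 2 (74), 3 (40) and 4 (92). Gastrocnemius at 4 days (74) spanned 15 to 78, outside 1.5 times without treated 1 (19) and PBS 1 (20), 2 (34), 3 (23) and 4 (15). Quadriceps at 1 day (81) spanned 16 to 144, outside 1.5 times without treated 1 (38), 2 (16), 3 (144) and 4 (26) and PBS 1 (47), 2 (27), 3 (35) and 4 (31). Quadriceps at 2 days (255) spanned 102 to 221, outside 1.5 times without treated 1 (163), 3 (128) and 4 (102) and PBS 1 (169), 3 (126) and 4 (114). Quadriceps at 4 days (1199) spanned 792 to 1334, outside 1.5 times without treated 3 (792). Quadriceps at 7 days (1835) spanned 1211 to 1719, outside 1.5 times without treated 4 (1211). Total RNA at 2 days (82) spanned 12 to 161, outside 1.5 times without treated 1 (161), 2 (12) and 3 (19) and PBS 1 (42), 2 (20), 3 (25) and 4 (20). Nascent RNA at 1 day (146) spanned 24 to 266, outside 1.5 times without treated 1 (266), 2 (24) and 3 (47) and PBS 1 (62), 2 (44) and 4 (72). Nascent RNA at 2 days (869) spanned 534 to 1361, outside 1.5 times without treated 1 (1361) and PBS 2 (578) and 4 (534). Quadriceps at 3 months (1037) spanned 0 to 3876, outside 1.5 times without treated 1 (3876), 2 (3), 3 (2), 4 (2) and 5 (0) and PBS 1 (0), 2 (1), 3 (338) and 4 (3).

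The index of gastrocnemius at 1 day (0.8) spanned -1.0 to 5.0, and was -1.0 without treated 2 or treated 4 and -0.5 without PBS 4. The nascent minus total difference (6.8) spanned 5.9 to 8.4, and passed p = 0.05 only without either 2-day library of replicate 1 (8.4, exact p = 0.0159), with exact p from 0.0635 to 0.0952 in the other 18 of 20 cases. For the other indices no library changed the sign, nor the side of the threshold where the exact test of the smaller groups can go below p = 0.05. Leaving 1 library out of 4 against 4 leaves a smallest exact p of 0.0571, so 120 values reported at p under 0.05 have no such test, and they moved by less than the replicate SD.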

Other observations

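The genes below were chosen after their values were seen, and no explanation was tested for them. Meg3, Rian and Mirg, noncoding RNAs of 1 imprinted cluster that are made from the maternal allele, moved together in several cohorts. In gastrocnemius at 7 days Rian stood at 20.9 ± 4.23 TPM in FVB, 112 ± 17.4 in HSALR PBS, 26.9 ± 8.42 with EEV4-PMO at 15 mg/kg and 18.5 ± 3.06 at 30 mg/kg (SD, n = 4, 8, 4 and 4), and with unconjugated PMO at 136 ± 29.1. In quadriceps the log2 change of Rian against PBS was -0.47 at 1 day, -1.17 at 2 days, -2.43 at 4 days and -3.34 at 7 days (adjusted p = 0.63, 0.05, 2.6e-05 and 7.8e-07), with Mirg at -0.59, -0.97, -1.92 and -2.44. At 3 months Rian was at -1.70, Meg3 at -1.36 and Mirg at -1.24 (adjusted p = 0.028 each), but rescaling ended all 3 calls (-1.52, -1.17 and -1.09, adjusted p = 0.14, 0.093 and 0.08), and the gene count there hung on single libraries. In gastrocnemius at 4 days the values were -0.86, -0.39 and -0.78 (adjusted p = 0.17, 0.5 and 0.27).

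Clock genes differed between treated and PBS quadriceps at more than 1 day. Dbp was at 1.30, 1.06 and 1.41 and Per3 at 1.12, 1.01 and 1.27 at 1, 2 and 7 days (adjusted p = 0.013, 0.023 and 5.4e-04 for Dbp, and 0.0038, 0.0054 and 1.1e-04 for Per3), while Per3 in FVB quadriceps stood at 0.70 (adjusted p = 0.011). At 4 days, the day of the PBS group, neither was called (Dbp 0.69, adjusted p = 0.076, and Per3 0.57, adjusted p = 0.051). After rescaling Per3 was called there (0.57, adjusted p = 0.045) and Dbp was not (0.70, adjusted p = 0.11), and Dbp at 2 days had an adjusted p of 0.05. The labels give 1 PBS group, of 4 days, for all days of the time course, and the hour at which muscles were taken is not given in the sources used here.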
